A study of Mus musculus with 2 samples.

How the data were processed

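Total RNA sequencing of adrenal glands from male B6CASTF1/J mice aged 25 days was analysed, with 1 group of 2 libraries. Per the labels, RNA was purified from tissue, 300 ng went into a directional kit library, ribosomal RNA was reduced, and ERCC spike-ins were added. Replicate numbers are those of the labels. The labels disagree on the animals: the biosample labels give animal 3 and animal 4, and the library labels give animal 3 for both. Both libraries also carry the same donor label. That the replicates are separate animals therefore rests on the biosample labels.

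Each library had a gene table and a transcript table from a first quantification and a transcript table from a second. Per the text files deposited with each sample, all used the mm10 assembly and annotation M21, the first started from an alignment to the transcriptome and the second from the reads and an index. The names and versions of the aligner and of both quantifiers are not given in the sources used here, nor whether counting used the strand. The first tables hold expected counts, TPM and FPKM per gene and the percent of the gene's TPM on each transcript, all made by the authors, per the file headers. The second holds the authors' estimated counts and TPM per transcript, per the file headers. The deposited FPKM values were not used in any result. The authors' TPM of the first quantification was relative to genes, spike-ins and other listed sequences together and summed to a fixed total, so abundant short RNAs lower the TPM of all other genes. The deposited posterior SD of each count was used to describe reads shared between genes. The first quantification subtracted 99 nt from transcript lengths to give effective lengths, and the second subtracted 328 and 330 nt. The second lists 141864 transcripts and the first 168207, and 86 genes of the first are not in the second.

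The first gene table holds 55536 annotated genes, 96 ERCC spike-ins, 1 phiX sequence and 26248 entries with a number in place of a gene name. All 55536 gene identifiers matched the GENCODE M21 annotation, which gave symbols, biotypes and coordinates. Entries that name no gene stayed out of library sizes and tests. Spike-ins held 0.839% and 0.915% of counts, phiX had 0 counts, and the entries with numbers had 8 and 6.73 counts. In the first quantification replicate 1 held 35283841 expected counts and replicate 2 held 35156690.03, of which 34987819 and 34835147 were on annotated genes. Values of the second were summed over the transcripts of each gene. For list levels, identifiers that share a symbol were summed, which concerned Nnt and Rmrp, and such symbols stayed out of the per-gene test of lists and of list medians.

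Before the data were examined, 29 gene lists with 311 genes were fixed: steroidogenic, sex steroid, zona glomerulosa, zona fasciculata, X-zone, capsule and stroma, chromaffin, Schwann and sustentacular, endothelium, macrophage, lymphocyte, erythroid, white adipocyte, brown adipocyte, kidney, liver, skeletal muscle, pancreas, cholesterol synthesis, proliferation, immediate early, glucocorticoid response, circadian clock, imprinted, interferon, antioxidant, sex check, long non-coding RNA and small structured RNA. The genes named in the text were chosen by a rule fixed at the same time. It takes the 4 members of each list with the highest mean TPM (2 for lists of tissues that should be absent), a set of 20 adrenal and control genes, the 15 genes with the highest mean TPM, the 10 highest and 10 lowest ratios between the libraries among genes that pass the test, differ at least 2-fold and have a mean TPM of at least 5, and the 5 largest ratios each way between the quantifications among genes with a mean TPM of at least 10 in either. Genes named outside the rule were chosen after their values were seen: Por, Stard4, Fdx1, Scarb1, Mrap, Ddc, Gata3, H19, Snrpn, Alas2, Retn, Junb, Sod2, Lrp2, Aqp2, Apoe, Trf, Mup22, Eef1a1, Adh1, Atp5b, Apoc1, Cyp2e1, Ahsg, Fga, Myl1, Sln and the Akr1c genes other than Akr1c18. For the erythroid and both adipocyte lists 4 members were named in place of 2, also after their values were seen. Some genes that the rule takes are not reported here.

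Levels are TPM of the first quantification, as the mean ± SD of the 2 libraries, or as both values where they differ most. A gene was counted as detected at a TPM of at least 1 in both libraries. Shares are percent of summed TPM. Shares of counts of a single library have 95% exact Clopper-Pearson intervals. With 2 libraries in 1 group no test between groups is possible, and a comparison of the libraries has 1 library on each side and so no residual degrees of freedom. Between the libraries, expected counts were rounded to whole numbers, and each gene with at least 10 counts in total was given a two-sided exact binomial test (2 times the smaller tail) against library sizes scaled by the TMM method of edgeR 4.0.16, with factors of 1.08 and 0.923. P-values were adjusted by the Benjamini-Hochberg method at 0.05, over all genes and again over each list alone, and calls of differing genes also needed a 2-fold difference. Log2 ratios are replicate 2 over replicate 1 with a prior count of 0.5. A ratio against 0 counts is given as a bound against a floor of 3 counts per library. The median log2 ratio of each list with at least 5 members of a mean TPM of at least 1 was placed among 10000 random lists matched on mean expression in 20 bins. The difference of the steroidogenic and chromaffin medians was given a 95% interval from 10000 bootstrap draws. Agreement across genes was measured on log2(TPM + 1), and a chi-square test of rounded counts asked whether the libraries differ by more than sampling noise.

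Alternatives fixed before the data were examined were the second quantification, TPM over nuclear protein-coding genes alone, expected counts in place of TPM, other TPM thresholds, a pseudocount of 0.1, size factors of DESeq2 1.42.0 (1.08 and 0.923), total counts and spike-in totals in place of TMM, other count filters and folds, and each library left out. Leaving out each library for the markers of other tissues was added after seeing the data. Choices made after seeing the data were the prior count, the two-sided form of the exact test, library sizes over annotated genes only, the use of the mean TPM of the libraries for a TPM of at least 1 in either quantification, the length classes, the 10 percentage points for isoform shares, the division by the median ratio between quantifications, the test of list members and the counts of directions under total counts and spike-in totals, the patterns weighed, the summing of identifiers that share a symbol, and second lists of 25 liver and 20 muscle genes. These second lists were written after the first liver and muscle lists had been seen and before any value of their own genes was examined.

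The steps were tested on simulated data, drawn as Poisson counts around the mean of both libraries, which is the counting error that the test assumes. With 19852 simulated genes, of which 50 each were changed 2.5-fold, 0.4-fold, 4-fold and 0.25-fold, the test recovered 50, 44, 50 and 47, and it called 2 of 19652 unchanged genes. The chi-square test on 2 Poisson draws with the same mean gave 1.01 per degree of freedom, and 2 of 100 unshifted lists of random genes lay outside the central 95%. The real libraries gave 288 per degree of freedom, so these simulated error rates check the steps and do not carry over to the real libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.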

Results

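Total RNA of the adrenal gland was sequenced from male mice of the B6CASTF1/J strain, a first-generation cross of a laboratory strain with a wild-derived one, at 25 days of age. There was 1 group of 2 libraries, each made from 300 ng of RNA depleted of ribosomal RNA, with ERCC spike-in transcripts added. The design holds no comparison between conditions, so the results are the levels of genes in this tissue and the spread between the libraries. The biosample labels name animal 3 for replicate 1 and animal 4 for replicate 2, while the library labels name animal 3 for both, and both carry the same donor label. Tests between the libraries therefore measure the difference between these libraries, which may be technical. Replicate 1 held 35283841 expected counts and replicate 2 held 35156690.03. Of 55536 annotated genes, 13119 had a length-scaled level (TPM) of at least 1 in both libraries, and 11914 of these were nuclear protein-coding genes.

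The first question was how strongly the genes of the adrenal cortex and medulla were expressed. All 19 genes of the steroidogenic list, which covers cholesterol supply, steroid production and its regulators, had a TPM of at least 1 in both libraries. Together they took 1.17% ± 0.476 of all TPM (SD, n = 2), with 1.503% in replicate 1 and 0.831% in replicate 2. Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase (ENSMUSG00000027871.16, mm10 chromosome 3, 98852194 to 98859794), was the highest of them at 2710 ± 983 TPM. Star, which moves cholesterol into mitochondria (ENSMUSG00000031574.8, chromosome 8, 25806555 to 25815982), was at 2553 ± 1008 TPM. In the second quantification Star was above Hsd3b1 in both libraries, at 6440 and 3523 TPM against 5837 and 3319 TPM. The side-chain cleavage enzyme Cyp11a1 was at 1571 ± 647 TPM and the 21-hydroxylase Cyp21a1 at 1493 ± 712 TPM. The transcription factor Nr5a1 was at 99.1 ± 42.7 TPM and the ACTH receptor Mc2r at 77.3 ± 23.3 TPM. The share depended on what TPM was relative to: it was 2.01% in the second quantification and 3.47% over nuclear protein-coding genes alone.

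Genes of the separate cortical zones were also measured. Cyp11b1, which completes corticosterone synthesis in the zona fasciculata (ENSMUSG00000075604.5, chromosome 15, 74834125 to 74841643), was at 1423 TPM in replicate 1 and 715.1 TPM in replicate 2. Its paralog Cyp11b2, the aldosterone synthase of the zona glomerulosa (ENSMUSG00000022589.7, chromosome 15, 74851010 to 74856318), was at 59.0 and 42.7 TPM. The log2 ratio of the pair was 4.33 ± 0.37 (SD, n = 2), many times the spread between the libraries. The paralogs share some reads, and the second quantification gave a log2 ratio of 3.61. Akr1b7, at 1394 and 420.6 TPM, and Abcb1b, at 714.8 and 537.9 TPM, were the other abundant zona fasciculata genes. All 10 zona glomerulosa genes had a TPM of at least 1 in both libraries, led by Kcnk3 at 259 ± 66.6 TPM, Dab2 at 147 ± 60.5 TPM and Agtr1a at 119 ± 57.3 TPM. Of the sex steroid genes, 3 of 7 reached that level: Srd5a2 at 117 ± 35.6 TPM, Srd5a1 at 9.86 ± 4.30 TPM and the 17-alpha-hydroxylase Cyp17a1 at 1.18 and 1.73 TPM. Hsd17b1 was at 0.61 and 0.45 TPM.

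The X-zone is the transient innermost part of the mouse adrenal cortex. Its marker Akr1c18 (ENSMUSG00000021214.14, chromosome 13, 4132615 to 4150654) was at 526.6 TPM in replicate 1 and 75.4 TPM in replicate 2. The mean of 301 ± 319 TPM (SD, n = 2) is no larger than its spread, so 2 libraries do not fix its level. Thrb was at 15.2 and 14.2 TPM and Pik3c2g at 1.36 and 4.34 TPM.

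Chromaffin cells make catecholamines in the medulla, and 27 of 28 genes of their list had a TPM of at least 1 in both libraries. The list took 0.184% ± 0.0453 of all TPM (SD, n = 2), 0.320% in the second quantification and 0.545% over nuclear protein-coding genes alone. The granule proteins Chgb, at 490.0 ± 115 TPM, Chga, at 476 ± 118 TPM, and Scg2, at 194 ± 47.5 TPM, were highest. Of the catecholamine enzymes, Th was at 154 ± 45.9 TPM, Pnmt at 133 ± 63.7 TPM and Dbh at 86.6 ± 19.9 TPM. The summed steroidogenic list exceeded the summed chromaffin list by 2.62 ± 0.25 on the log2 scale (SD, n = 2), many times the spread between the libraries.

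**Figure D1:**
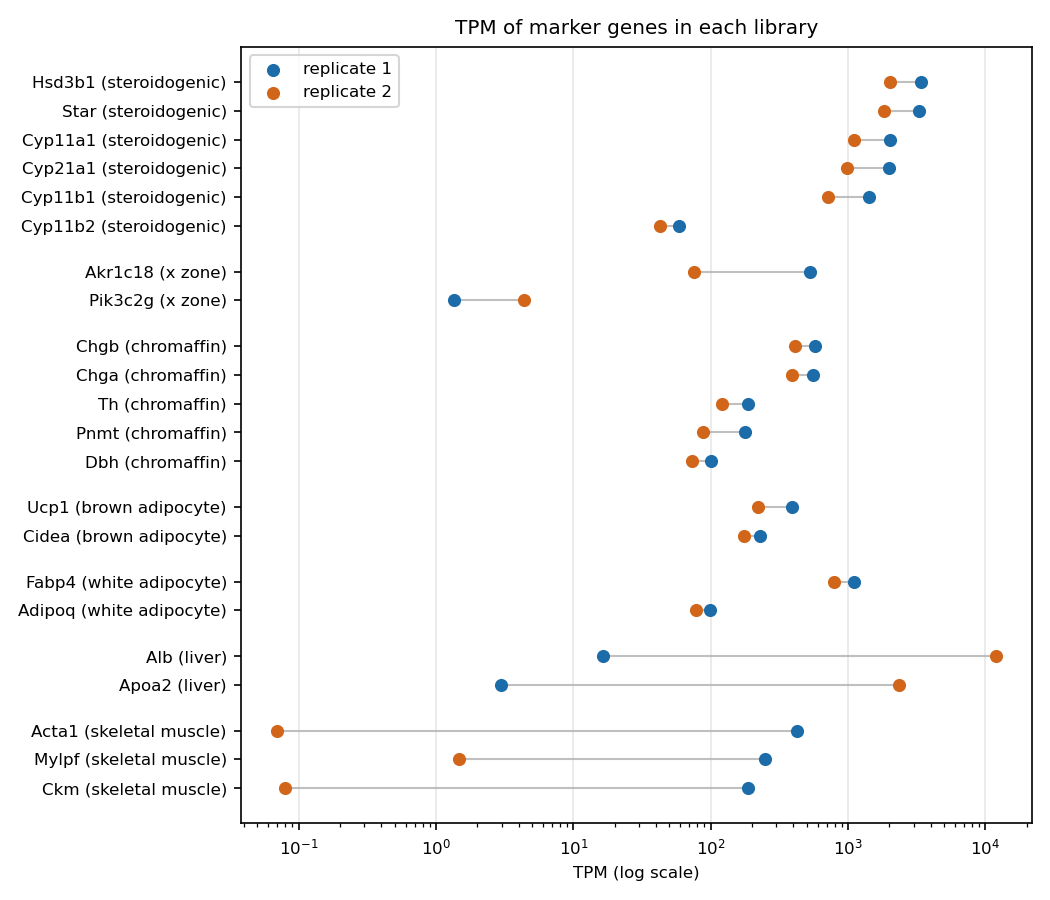
TPM on a log axis (horizontal) of named marker genes (vertical), with a point for each of the 2 libraries and a grey line joining them. Steroidogenic and chromaffin genes differ little between the libraries beside Alb, which is at 16.3 TPM in replicate 1 and 11949 TPM in replicate 2, and Acta1 at 425.6 and 0.07 TPM.

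The next question was which other tissues and cell types left transcripts in the libraries. All 6 liver genes were at least 10-fold higher in replicate 2. Alb, serum albumin (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), was at 16.3 TPM in replicate 1 and 11949 TPM in replicate 2, and the apolipoprotein Apoa2 was at 2.97 and 2362 TPM. The liver list summed to 0.00258% of TPM in replicate 1 and 1.84% in replicate 2. All 6 skeletal muscle genes were at least 10-fold lower in replicate 2: skeletal muscle actin, Acta1, was at 425.6 and 0.07 TPM and the myosin light chain Mylpf at 246.9 and 1.46 TPM. The muscle list summed to 0.117% of TPM in replicate 1 and 0.000191% in replicate 2. All of these passed the exact binomial test between the libraries, 6 and 6 over all genes and 6 and 6 adjusted over the list alone.

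Fat transcripts were present in both libraries. All 7 white adipocyte genes had a TPM of at least 1, led by Fabp4 at 951 ± 221 TPM, Car3 at 591 ± 52.0 TPM, Cfd at 320.0 ± 58.0 TPM and Plin1 at 173 ± 29.2 TPM. All 5 brown adipocyte genes did so as well, with Cox8b at 458 ± 120 TPM, the uncoupling protein Ucp1 at 305 ± 122 TPM and Cidea at 201 ± 39.4 TPM, while Elovl3 was at 6.33 and 35.8 TPM. Haemoglobin transcripts were abundant: Hba-a1 was at 1685 ± 545 TPM, Hbb-bs at 1485 ± 469 TPM, Hba-a2 at 1326 ± 353 TPM and Hbb-bt at 192 ± 39.5 TPM, with near-identical copies that share reads. None of the 8 kidney genes reached a TPM of 1 in either library. Of the 6 pancreas genes only Cela1 did, at 17.7 ± 0.113 TPM, and Cpa1 was at 0 and 0.1 TPM, where 0 counts allow up to 0.0836 TPM. Over these 7 lists of other tissues, 24 of 45 genes had a TPM of at least 1 in both libraries.

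Vessels and immune cells were seen at lower levels. All 10 endothelial genes had a TPM of at least 1 in both libraries, led by Egfl7 at 59.2 ± 7.82 TPM, Plvap at 52.8 ± 10.9 TPM, Emcn at 31.5 ± 7.35 TPM and the VEGF receptor Kdr at 26.3 ± 2.72 TPM. The same held for all 10 macrophage genes, led by Cd74 at 37.1 ± 10.8 TPM, Lyz2 at 35.5 ± 5.02 TPM, C1qb at 18.7 ± 1.31 TPM and C1qa at 16.9 ± 2.47 TPM. None of 7 lymphocyte genes reached a TPM of 1. Of 11 capsule and stroma genes 10 did, with the collagens Col3a1 at 86.4 ± 0.658 TPM, Col1a2 at 52.9 ± 7.35 TPM and Col1a1 at 52.0 ± 3.99 TPM and the proteoglycan Dcn at 61.8 ± 3.38 TPM. Of 7 Schwann and sustentacular genes, 2 reached it in both libraries, among them S100b at 7.80 ± 2.12 TPM, while Erbb3 was at 0.95 and 13.1 TPM, and Sox10 at 0.56 ± 0.0566 TPM. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at 25.6 ± 6.00, 25.1 ± 4.51, 9.76 ± 1.92 and 6.42 ± 1.54 TPM, and Xist was at 0.03 TPM in both libraries.

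In the first quantification a few short and mitochondrial RNAs took most of the TPM, which did not hold for the short RNAs in the second. The 7SL RNA genes Rn7s1 and Rn7s2, between which shared reads were divided equally, each had a mean of 147028 TPM and together took 29.4% ± 0.0538 of all TPM (SD, n = 2), but 5.73% of counts in replicate 1 and 5.70% in replicate 2. Mitochondrially encoded genes took 16.5% ± 0.432 of TPM (27.3% in the second quantification), led by the ribosomal RNAs mt-Rnr2 at 58709 TPM and mt-Rnr1 at 52375 TPM, with mt-Co1 at 11288, mt-Cytb at 7113 and mt-Atp6 at 5327 TPM. The others among the 15 highest genes were Rn7sk at 40859 TPM, Gm26917 at 13595 TPM, the pseudogenes Gm28661, Gm10925 and Gm28437 at 12642, 9504 and 7233 TPM, Rpph1 at 6932 TPM, Alb, and Malat1 at 5357 ± 1113 TPM. These pseudogenes lie side by side on chromosome 1, from 24613189 to 24615565. In replicate 1 Gm10925 was at 9762 TPM in the first quantification and 1230 TPM in the second, while mt-Atp6 was at 4965 and 19236 TPM. The other pseudogenes were higher in the second, in replicate 1 at 12597 and 22344 TPM for Gm28661 and 7555 and 11764 TPM for Gm28437. The median ratio of nuclear protein-coding genes between the quantifications was 1.73 there, so a higher TPM in the second was common to most genes. Whether the pseudogenes take reads of mitochondrial genes was not tested, so the levels of both are uncertain. Rmrp, summed over its 2 identifiers, was at 7620 ± 112 TPM. The long non-coding RNAs Meg3, Neat1 and Gas5 were at 354 ± 97.3, 279 ± 74.0 and 85.8 ± 25.2 TPM. Nuclear protein-coding genes held 32.8% of TPM in replicate 1 and 35.5% in replicate 2, but 60.8% and 62.6% in the second quantification, where Rn7s1 and Rn7s2 together held 0.000402% and 0.000168%. Spike-ins took 0.839% of counts in replicate 1 (95% exact Clopper-Pearson interval 0.836% to 0.842%) and 0.915% in replicate 2 (0.911% to 0.918%), and these intervals cover counting error only.

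The libraries were then compared gene by gene. Among 826 genes that differed at least 2-fold, passed the test and had a mean TPM of at least 5, 746 were higher in replicate 2 and 80 lower. The 10 highest ratios belonged to Mup17, Sult3a2, C9, Ugt2b35, Hsd3b5, Cyp7a1, Acsm1, Cyp4a12b, Fabp1 and BC025446. Mup17, of the major urinary protein family with its near-identical copies, had 0 counts in replicate 1 and 6424 in replicate 2, and its log2 ratio in the second quantification was 10.25. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0 and 1385 counts, 545-fold higher against a floor of 3 counts, with a 95% counting interval from 442-fold upward. Fabp1, the liver fatty acid binding protein, had 5 and 12956 counts, a 2779-fold difference with a 95% counting interval of 1310 to 9416. The 10 lowest ratios belonged to Myh2, Acta1, Atp2a1, Myh4, Tnni2, Myh1, Ttn, Ckm, Actn2 and Pvalb, which include myosin heavy chains, titin and muscle creatine kinase. Myh2 had 5559 and 0 counts, 1571-fold lower in replicate 2 against that floor, with an interval from 1277-fold upward. Ttn had 81121 and 35 counts, a 1937-fold difference with an interval of 1413 to 2821.

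Across all tested genes, 7738 of 19801 passed a two-sided exact binomial test on TMM-scaled counts at a Benjamini-Hochberg adjusted p of 0.05. Of these, 1694 were at least 2-fold higher in replicate 2 and 452 at least 2-fold lower, so that 78.9% of 2146 were higher. That share was 66.6% of 2168 genes with total counts and 57.6% of 2346 genes with spike-in totals in place of TMM. The median log2 ratio (replicate 2 over replicate 1) of genes with a mean TPM of at least 1 was -0.01 with TMM, -0.25 with total counts and -0.37 with spike-in totals. With TMM, 90.2% of these genes lay within 2-fold. Over 55536 genes, Pearson's r of log2(TPM + 1) was 0.949 and Spearman's rho 0.924, and over the 14204 genes with a mean TPM of at least 1 they were 0.815 and 0.839; these are correlations across genes, which are not independent replicates. A chi-square test of the counts of 19801 genes gave 288 per degree of freedom, so the libraries differed by more than sampling noise. The test has 1 library on each side, covers counting error only and compares these libraries, not conditions.

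**Figure D2:**
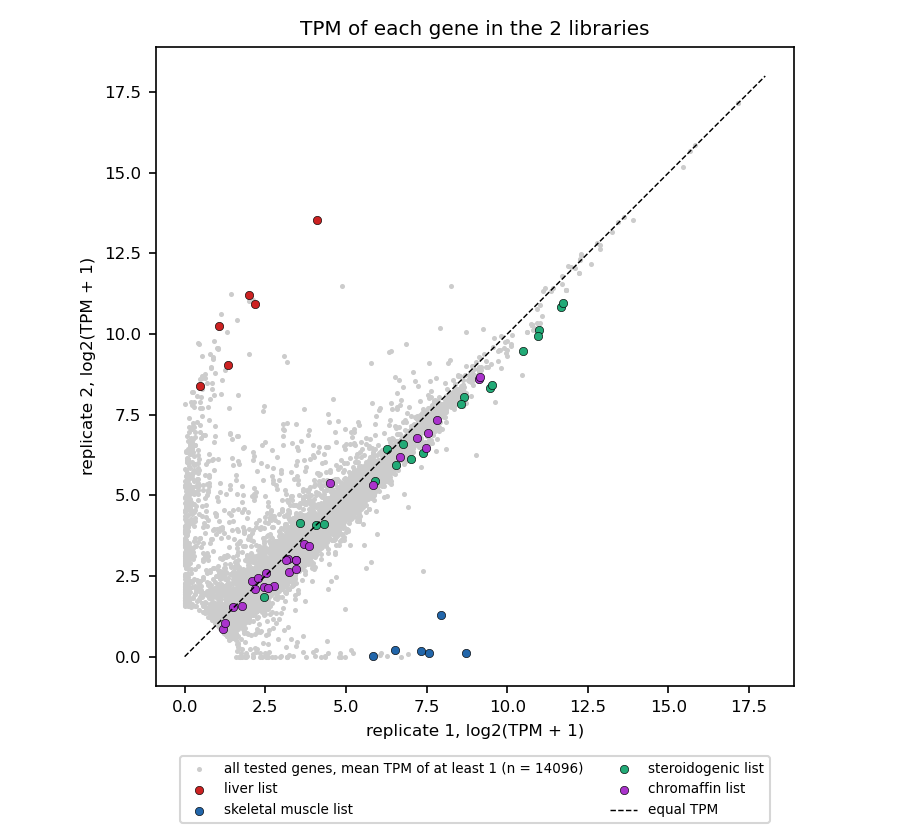
Each gene's log2(TPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), for 14096 tested genes with a mean TPM of at least 1 in grey and the members of 4 gene lists in colour, with a dashed line at equal TPM. The 6 liver genes lie far above the line and the 6 skeletal muscle genes along the horizontal axis.

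Adrenal genes differed less, and most were lower in replicate 2, the library with the liver transcripts, while replicate 1 held the muscle transcripts. Of 19 steroidogenic genes, 14 passed the test as lower and 3 as higher in replicate 2 at any fold, none of them 2-fold. The same number, 17, passed adjusted over the list alone. Log2 ratios were -0.53 for Hsd3b1, -0.63 for Star, -0.64 for Cyp11a1, -0.80 for Cyp21a1 and -0.76 for Cyp11b1. Stard4, at 0.75, and Por, at 0.37, were among the higher genes; 2 of the 3 higher genes passed as higher with total counts and 1, Stard4, with spike-in totals, where Por was at 0.01 and 1 passed as lower. The median of the list was -0.53, lower than all 10000 random lists matched on mean expression. With total counts 4 of the 19 genes were at least 2-fold lower: Fdx1 at -1.15, Scarb1 at -1.11, Mrap at -1.09 and Cyp21a1 at -1.03. With spike-in totals these 4 stayed so, and Cyp11b1, at -1.12, and Nr5a1, at -1.03, brought the number to 6.

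The chromaffin genes were also lower in replicate 2, beside the liver transcripts there and the muscle transcripts in replicate 1. Their median log2 ratio was -0.25, lower than all random lists. Of 28 genes, 16 passed as lower and 4 as higher, and 20 passed adjusted over the list alone. Ddc, at 1.15, was the 1 member at least 2-fold different, though not with total counts, at 0.92, or spike-in totals, at 0.79. Of the 4 higher genes, 3 passed as higher with total counts and 1, Ddc, with spike-in totals, where Gata3 was below 0. Chgb was at -0.25, Chga at -0.28, Th at -0.39 and Pnmt at -0.79, which passed 2-fold with total counts, at -1.02, and with spike-in totals, at -1.14. The zona glomerulosa median was -0.29 (percentile 0.16 among random lists), with 7 of 10 genes lower, or 9 passing adjusted over the list alone. All 4 zona fasciculata genes were lower, 4 also adjusted over the list alone, with Akr1b7 at -1.50 (95% counting interval -1.53 to -1.48). All 3 X-zone genes passed, 3 also adjusted over the list alone: Akr1c18 was lower at -2.57 (-2.63 to -2.52), Pik3c2g was higher at 1.38, and Thrb was higher at 0.19 with TMM, did not pass with total counts and was lower with spike-in totals. Of the sex steroid genes, Srd5a2, Srd5a1 and Cyp17a1 were higher, at 0.86, 1.14 and 0.70, though Cyp17a1 did not pass with total counts or spike-in totals, and 3 passed adjusted over the list alone.

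Of the immune and metabolic lists, 3 were higher in replicate 2, the library with the liver transcripts, while replicate 1 held the muscle transcripts. The interferon median was 0.69 (percentile 99.98), with 10 genes higher and 1 lower, and 12 passing adjusted over the list alone. Bst2 was at 20.3 and 41.2 TPM, Stat2 at 11.1 and 18.1 TPM and Irf9 at 8.19 and 10.1 TPM, and of the 10 higher genes 7 passed as higher with total counts and 6 with spike-in totals. The macrophage median was 0.56 (percentile 99.89), with 8 of 10 genes higher, 8 adjusted over the list alone, of which 7 passed as higher with total counts and 5 with spike-in totals. The cholesterol synthesis median was 0.46, higher than all random lists, with 16 genes higher and 4 lower and 20 adjusted over the list alone; of the 16, 13 passed as higher and 1 as lower with total counts, and 10 as higher and 3 as lower with spike-in totals. Fdps, lower with either, was at 91.9 and 84.9 TPM and Hmgcs1 at 101.1 and 87.3 TPM, and Dhcr7, at 235.5 and 125.9 TPM, was among the lower genes. TMM scaling, unlike TPM, places the median gene near 0, so a gene such as Fdps was higher by the test with TMM at a slightly lower TPM.

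Imprinted genes, several of them growth regulators of the fetus, were lower in replicate 2. Muscle transcripts moved the same way, at 0.117% of TPM in replicate 1 and 0.000191% in replicate 2, and liver transcripts the other way, at 0.00258% and 1.84%, as they did for the erythroid and long non-coding lists. With 2 libraries every gene that differs moves with liver or with muscle, so this ties no list to either tissue. The imprinted median was -0.32, lower than all random lists, with 17 genes lower and 1 higher (Snrpn, which did not pass with total counts or spike-in totals), and 19 passing adjusted over the list alone. Gnas was at 837 ± 223 TPM, Rian at 174 ± 40.8 TPM and Dlk1 at 160.0 ± 47.7 TPM, and H19 had the lowest ratio at -2.72 (54.4 and 6.71 TPM). The erythroid median was -0.32 (percentile 1.26), with 4 genes lower, 1 higher (Alas2, which did not pass with total counts or spike-in totals) and 5 adjusted over the list alone, and the median of long non-coding RNAs was -0.26 (percentile 1.30), with 6 lower and 6 adjusted over the list alone. The liver and skeletal muscle medians were 9.78 and -10.18. In all, 11 of 21 lists lay outside the central 95% of random lists, 7 below and 4 above.

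**Figure D3:**
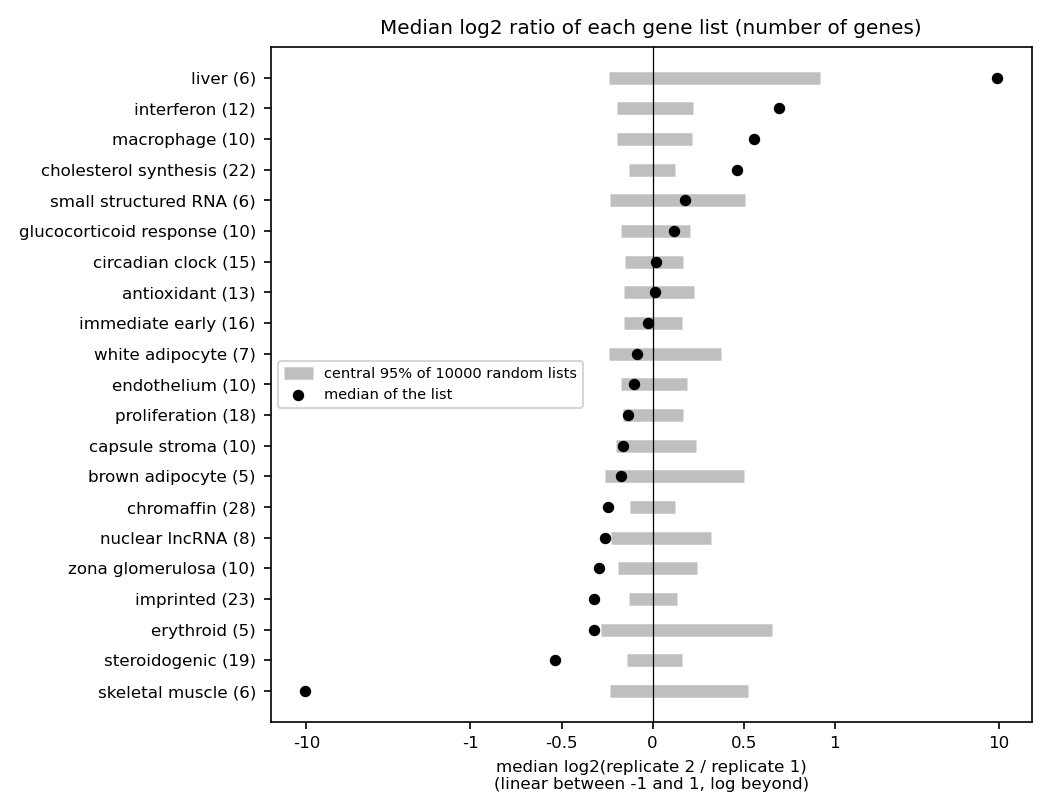
Median log2 ratio (replicate 2 over replicate 1) of 21 gene lists as points, with the central 95% of 10000 random lists matched on mean expression as grey bars, on an axis linear between -1 and 1 and logarithmic beyond. The liver list lies at 9.78, the skeletal muscle list at -10.18, and the steroidogenic list, at -0.53, below its bar; the small structured RNA, glucocorticoid response, circadian clock and antioxidant medians turn negative with total counts or spike-in totals.

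The other 10 lists lay inside that range. Genes higher in replicate 2 moved with the liver transcripts, at 0.00258% of TPM in replicate 1 and 1.84% in replicate 2, and lower ones with the muscle transcripts, at 0.117% and 0.000191%. With 2 libraries this holds for every gene that differs, here and below, so it ties none of them to either tissue. The proliferation median was -0.14 (percentile 4.77), with 5 of 18 genes lower and 5 adjusted over the list alone; Pcna was at 35.4 and 20.9 TPM, Mcm2 at 13.8 and 10.3 TPM, Mcm6 at 12.8 and 8.94 TPM and Tyms at 9.41 and 7.92 TPM. The endothelial median was -0.10 (6 lower, 1 higher and 7 adjusted over the list alone), the capsule and stroma median -0.16 (4 lower, 3 higher and 8 adjusted over the list alone; of the 3, Dcn alone passed as higher with total counts and none with spike-in totals, while Col1a1 was lower with either and Col3a1 with spike-in totals), the white adipocyte median -0.09 (4 lower, 3 higher, of which Retn did not pass with total counts or spike-in totals, and 7 adjusted over the list alone) and the brown adipocyte median -0.17 (4 lower, 1 higher and 5 adjusted over the list alone). Of 19 immediate early genes, 6 were lower and 5 higher, of which Junb did not pass with total counts or spike-in totals, 11 adjusted over the list alone. Nr4a1 was higher at 12.3 and 30.8 TPM, Hspa1b lower at 21.4 and 6.36 TPM and Myc lower at 17.9 and 10.8 TPM, and Jun, at 45.5 ± 5.03 TPM, did not pass. Of 10 glucocorticoid response genes, 3 were lower and 5 higher, 9 adjusted over the list alone, with Errfi1, which moved with the liver transcripts, at 9.03 and 98.2 TPM, Mt1 at 60.8 ± 8.80 TPM, Mt2 at 36.5 ± 0.636 TPM and Sgk1 at 34.5 ± 11.8 TPM. Of the 5 higher genes 1, Errfi1, passed as higher with total counts or spike-in totals.

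Of 16 clock genes, 4 were lower and 4 higher, 9 adjusted over the list alone, and 1 of the 4 higher genes, Dbp, passed as higher with total counts or spike-in totals. Nr1d1 was at 36.5 ± 4.76 TPM, Dbp at 25.5 ± 3.13 TPM, Bhlhe40 at 24.8 ± 0.841 TPM and Tef at 22.4 ± 4.31 TPM. Of 13 tested antioxidant genes, 5 were lower and 6 higher, of which Sod2 turned lower with total counts or spike-in totals, 11 adjusted over the list alone. Catalase, Cat, was at 135.2 and 451.5 TPM, Gpx1 at 190.3 and 543.9 TPM, both higher like the liver transcripts, at 0.00258% and 1.84% of TPM, Sod1 at 467 ± 66.6 TPM and Gpx4 at 368 ± 39.8 TPM. Nnt, the mitochondrial transhydrogenase, was at 29.4 ± 5.22 TPM summed over its 2 identifiers, between which the quantifications split the reads differently. Of 6 tested small structured RNAs, 3 were higher and 1 lower, 4 adjusted over the list alone, and none of the 3 passed as higher with total counts or spike-in totals, where Rn7s1 and Rn7s2 were lower. Rn7s1 and Rn7s2 each had 1010875 counts in replicate 1 and 1001257 in replicate 2, so they are not separate measurements. The posterior SD of each count was 2.45% and 2.11% of it, which the test leaves out. Of the Y-linked and X-inactivation genes, Ddx3y passed as lower, and 1 passed adjusted over the list alone. Of the Schwann and sustentacular genes, S100b was lower and Erbb3 higher, and 2 passed adjusted over the list alone. Of the kidney genes, Lrp2, at 0.11 and 0.21 TPM, was higher, with 1 adjusted over the list alone, and Aqp2 was at 0.4 and 0.27 TPM. None of the 6 tested lymphocyte genes passed, nor did Cela1, the 1 tested pancreas gene; 0 passed in either list adjusted over the list alone.

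The last question was how far the values depend on the quantification, since each library came with 2 transcript tables. Short RNAs differed most. Rn7s1, Rn7s2, Rn7sk, mt-Atp8 and Rmrp, of 204 to 331 nt, were the 5 lowest in the second relative to the first: Rn7s1 was at 147218 TPM in replicate 1 in the first and at 2.01 TPM in the second, and mt-Atp8, at 4980 TPM in the first, was at 0. The 5 highest were Gm47283, Gm28439, Hist2h2aa1, Gm12840 and Gm47571. Of 16241 genes with a mean TPM of at least 1 in either, 3035 were at least 2-fold higher and 534 at least 2-fold lower in the second in both libraries. The median ratio over nuclear protein-coding genes was 1.73 in replicate 1 and 1.66 in replicate 2, and after division by it 515 genes were higher and 613 lower. Of genes with a mean TPM of at least 10 and a longest transcript under 300 nt, 158 of 158 kept less than 10% of their reads in the second, against 62 of 125 from 300 to 500 nt and 39 of 6490 at or above 500 nt. Among protein-coding genes alone these were 3 of 3, 4 of 43 and 13 of 6331. From 300 to 500 nt, length alone therefore did not separate lost from kept genes. Isoform shares were also compared: of 10 steroid and catecholamine genes with more than 1 transcript, the share of the leading transcript was within 10 percentage points between the quantifications in both libraries for 7, among them Star, Cyp11a1 and Chga. The exceptions were Nr5a1, Hsd3b1 and Th, and the widest gap was that of Nr5a1, where transcript ENSMUST00000028084.4 held 81.2% of TPM in replicate 2 in the first and 8.76% in the second.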

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

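Entries of the first gene table with a number in place of a gene name were used in no comparison. They held 8 expected counts in replicate 1, on 2 of 26248 entries, and 6.73 in replicate 2, on 4 entries. They were flagged because each sum is above the floor of 3 counts. That floor is for a single gene and is no bound for a sum over many entries. The entries span 61 to 259 nt, and what they stand for is not given in the sources used here.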

How the results depend on the processing

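Leaving out each library for the markers of other tissues was chosen after the results were seen. No paired analysis was possible because the series has 1 group. In the second quantification the steroidogenic share was 2.01%, the chromaffin share 0.320%, the mitochondrial share 27.3% and the Cyp11b1 to Cyp11b2 log2 ratio 3.61. Over nuclear protein-coding genes alone the steroidogenic share was 3.47%, the chromaffin share 0.545% and Akr1c18 was at 909.8 TPM, since fewer genes share the total; this setting does not apply to the mitochondrial share. With expected counts, not divided by length, the Cyp11b log2 ratio was 5.34. In TPM the spike-in share was 1.17%. Across genes with a mean TPM of at least 1, r was 0.815. In the second quantification Rn7s1 and Rn7s2 held 0.000402% and 0.000168% of TPM, against 29.4% in the first. Because TPM sums to a fixed total, such a loss raises the shares of all other genes. The median ratio of nuclear protein-coding genes between the quantifications was 1.73 in replicate 1 and 1.66 in replicate 2. The Cyp11b ratio does not depend on that total, and the cause of its change was not tested.

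Genes differing between the libraries numbered 1383 with at least 100 counts, where fewer genes were tested, and 7738 at any fold, against 2146; with total counts 1443 were higher and 725 lower, and with spike-in totals 1351 and 995. The quantifications differed in 2243 genes at a TPM of at least 5 and in 12552 at 1.5-fold, against 3569. The 21 list medians had 62 values under DESeq2 size factors, a mean TPM of at least 5 or the second quantification. Of these, 59 kept their sign and their side of the central 95%, though DESeq2 factors move all genes alike and cannot change the side. The proliferation median was outside it in the second quantification, at -0.19. The immediate early median was 0.011 at a mean TPM of at least 5, and the circadian clock median was -0.030 in the second quantification. The cause of these changes was not tested. Total counts and spike-in totals were not among these settings. With total counts the glucocorticoid response, circadian clock, antioxidant and small structured RNA medians were -0.12, -0.21, -0.22 and -0.05. A set of 38 genes came from the fixed adrenal and control set and from the highest and lowest ratios between the libraries. Of their 228 values, 222 kept direction and side of the 2-fold threshold, 6 passed it with total counts or spike-in totals, and none reversed. Much of this was fixed in advance. Count filters cannot change a gene's own ratio, DESeq2 factors move all genes alike, and the highest and lowest ratios lay far beyond 2-fold. Members of other lists that no longer passed as higher or turned lower are named or counted with those lists. Losses of the 2-fold threshold are not all given there. Among these, Srd5a1 fell to 0.91 with total counts and 0.78 with spike-in totals, and interferon genes at least 2-fold higher fell from 3 to 1 and 0.

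With each library left out, the range was 0.831% to 1.503% for the steroidogenic share, 0.152% to 0.216% for the chromaffin share, 2.45 to 2.80 for the cortex to medulla log2 ratio, 4.07 to 4.59 for the Cyp11b log2 ratio, 75.4 to 526.6 TPM for Akr1c18, 16.2% to 16.8% for the mitochondrial share, 13831 to 14013 for genes detected and 25 to 29 for markers of other tissues. With 2 libraries, Akr1c18 moves by more than 1.5 times whichever is left out.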

Other observations

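Every test of an explanation here was chosen after its result was seen, except the test of the second liver list, which was written before the values of its genes were examined.

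Genes outside the fixed lists also separated the libraries. Apoe was at 304.1 TPM in replicate 1 and 2871 TPM in replicate 2, transferrin (Trf) at 28.1 and 2877 TPM and Mup22 at 1.73 and 2432 TPM, all among the 15 highest nuclear protein-coding genes. In the same set, the elongation factor Eef1a1 was at 1959 and 1757 TPM, Adh1 at 1766 and 1119 TPM and Atp5b at 1128 and 1014 TPM. A second list of 20 skeletal muscle genes went the way of the first: 19 of 19 tested genes were lower in replicate 2, 18 of them at least 10-fold, with a median log2 ratio of -9.21, or -8.55 with the 5 genes at 0 counts set to their bound. Its most abundant genes were Myl1, at 165.7 and 5.28 TPM, and Atp2a1, at 120.1 and 0.05 TPM, and Sln was at 0 in both libraries. Nuclear snRNAs took 4.67% of TPM in replicate 1 and 3.51% in replicate 2, and replication-dependent histone genes 0.200% and 0.152%.

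Liver transcripts were far higher in replicate 2, with Alb at 16.3 and 11949 TPM. Of a second list of 25 hepatocyte genes, 96% were at least 10-fold higher in replicate 2, which argues against a change of adrenal cells in a few liver genes and is consistent with liver tissue or liver RNA in that library. The most abundant were Ahsg, at 3.30 and 2129 TPM, Apoc1, at 240.8 and 1156 TPM, which was under 10-fold, Cyp2e1, at 83.4 and 717.7 TPM, and Fga, at 1.02 and 753.1 TPM. Cyp2e1 counted as 10-fold with TMM scaling, though its TPM differed by less. Of the 25 genes, 8 had a TPM of at least 1 in replicate 1. Whether liver entered at dissection or at a later step was not tested, and the design gives no group from which a biological explanation could be tested.

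Cortical genes were lower in replicate 2. Different assignment of reads to related genes is argued against by the second quantification, where the steroidogenic median was also -0.53. Dilution of adrenal RNA by RNA of other tissue predicts the same fall in cortex and medulla. The steroidogenic and chromaffin medians differed by -0.29, with a 95% bootstrap interval of -0.53 to 0.01. That interval just includes 0, also allows a sizeable difference, and treats the genes of each list as independent. Dilution alone would also lower every gene absent from the added tissue alike. Hsd3b1 was at -0.53 (95% counting interval -0.55 to -0.52), Star at -0.63 (-0.64 to -0.62) and Cyp21a1 at -0.80 (-0.81 to -0.78). Chgb was at -0.25 (-0.27 to -0.23) and Pnmt at -0.79 (-0.85 to -0.73). For these genes this argues against dilution as the whole cause, though the intervals cover counting error only. Dilution as a part of the cause stays open. A difference between animals in the amount of cortex may also contribute and was not tested.

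Akr1c18 was lower in replicate 2 by more than the genes of the steroidogenic, zona glomerulosa and zona fasciculata lists. Its log2 ratio of -2.57 lay below the lowest steroidogenic gene, at -0.91, and below the zona fasciculata gene Akr1b7, at -1.50, which argues against less cortex of every zone alike as the whole cause. For reads shared with other Akr1c genes, the test first written gave -0.27 for the summed family, above its bound of -1 and so in favour of sharing; it was set aside after that value was seen, because Akr1c6 (7 and 5641 counts) and Akr1c14 (28 and 3547 counts) were higher in replicate 2 like the liver genes and fill the sum. A test chosen in its place argues against sharing: the deposited posterior SD of the Akr1c18 count was 0 in both libraries, and the second quantification gave -2.62. Of the other X-zone genes, Pik3c2g was higher at 1.38, at low levels of 1.36 and 4.34 TPM. Thrb was higher at 0.19 with TMM, did not pass with total counts and was lower with spike-in totals. A rise in replicate 2 is also the direction of the liver transcripts there. These genes therefore cannot tell whether the X-zone differed as a whole, and what sets Akr1c18 apart stays open.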
